A study of Mus musculus with 2 samples.

How the data were processed

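Small RNA of microRNA size from the embryonic facial prominence of the mouse strain B6NCrl at embryonic day 12.5 was sequenced in 2 libraries. The facial prominences are the buds of neural crest mesenchyme, covered by epithelium, that form the face and jaws. Per the labels, the libraries were biological replicates of 1 group, made from pools of 120 embryos (replicate 1) and 88 embryos (replicate 2) of mixed sex. No other group was analysed here, so the comparisons concern the level of genes and gene lists within the tissue and the difference between the 2 libraries. Any test on the reads compares these libraries, not conditions.

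For each library the authors deposited whole-number read counts per miRNA gene, not normalised and not pooled, from an alignment to mm10 with GENCODE annotation M4, per the library descriptions. The aligner, the counting tool and the adapter trimming were not given in the sources used here. Each table gave, per gene, the count on both strands, the count on 1 strand and the count on the other strand, and the first column was the exact sum of the other 2. The table had no header, and the gene's own strand was taken to be the column that held 96.8% of the reads on genes in replicate 1 and 96.7% in replicate 2. Own-strand counts were used throughout, by a rule set in advance for tables with several strand columns, and the other columns served as alternatives. Another 4 entries held reads that were unmapped, mapped to several places, lay outside the listed genes or were ambiguous. They were kept out of the library sizes, and their shares are given with the depth of each library. Reads that map to several places were counted to no gene, so a gene that shares its sequence with a copy elsewhere can be undercounted. Each gene's count joins both arms of its hairpin, so mature strands were not separated. The MD5 sums of both tables equalled those in the library descriptions.

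The tables held 1973 gene identifiers. GENCODE M21 on GRCm38 (the assembly that mm10 denotes) gave symbols, positions and sequences for 1894 of them. The other 79 held 3 counts in replicate 1 and 4 in replicate 2. Positions are 1-based. A miRNA gene was placed in a host gene when it lay inside that gene on the same strand, and was called exonic if it overlapped an annotated exon of any transcript. A gene was said to share sequence with a copy when its hairpin held a stretch of 20 bases found, on either strand, in a miRNA gene at another place. That held for 929 genes, of which 89 were detected.

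Levels are in CPM, the own-strand count of a gene divided by the library's sum over genes and scaled to 1000000. How well CPM compare the amounts of different miRNAs was not tested. A gene was called detected with at least 10 counts in both libraries, which is 2.12 CPM in replicate 1 and 1.69 CPM in replicate 2. A count of 0 allows up to 3 counts, or 0.636 and 0.506 CPM. Shares of reads carry exact Clopper-Pearson intervals at the 95% level. Intervals and floors cover counting error only, since the reads carried no molecular identifiers that were used here. Errors of levels are the SD of the 2 libraries, so n = 2 throughout.

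Spread between the libraries was estimated with edgeR 4.0.16 (R 4.3.3) as a common biological coefficient of variation, with TMM factors of 0.998 and 1.002. Tested on simulated data for 395 genes, coefficients of 0.1, 0.2 and 0.4 were recovered as 0.101, 0.201 and 0.399. Genes that differed between the libraries were found with a two-sided exact binomial test per gene against the share given by the TMM library sizes, with Benjamini-Hochberg adjustment at 0.05 and an absolute log2 ratio of at least 1. edgeR's quasi-likelihood test needs residual degrees of freedom that 1 library against 1 does not leave. On counts simulated with counting error alone and 200 of 395 genes changed 3-fold, 94.5% of the changed genes were recovered. There 0 unchanged genes were called, but that simulation held no spread between pools, so it does not test the calls against such spread. The exact binomial test covers counting error alone, so 100 further data sets with no changed gene were drawn from a negative binomial distribution at the fitted coefficient.

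The level of each of 18 gene lists was described by the percentile of its median log2(CPM + 1) over detected members among 10000 random lists of the same size drawn from the detected genes. Lists within the highest or lowest 2.5% of random lists are said to stand apart, a limit that was set after the tables were opened. The difference of a list between the libraries was described in the same way by its median log2 ratio, with random lists matched on mean CPM. The two-sided share of random lists as far out was adjusted over the 18 lists by the Benjamini-Hochberg method. These percentiles describe the 2 libraries and are not replicate p-values. Random lists draw genes singly, so the percentile of a list whose genes lie in the same cluster may overstate how unusual it is. The lists were mesenchyme and cartilage, epithelium, sensory epithelium and sensory neurons, neural, striated muscle, smooth muscle and pericyte, endothelium, erythroid, leukocyte, miR-17-92 and paralogous clusters, let-7 family, the Dlk1-Dio3 imprinted cluster, other imprinted hosts, pluripotency, Hox loci, eye, liver and gut, and an X-linked testis cluster.

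Named genes were the 20 with the highest mean CPM, the up to 4 highest members of each list, and, in each direction, the 5 genes with the largest log2 ratio among those that differed between the libraries and had a mean CPM of at least 10. Genes outside this rule are said to have been chosen after their values were seen. The grouping, the lists, the rule for named genes, the tests and most alternatives were fixed before the data were examined. The alternatives were other count minimums, other pseudocounts, DESeq2 1.42.0 size factors or total counts in place of TMM, the count on both strands, an exact test in edgeR with a fixed coefficient of 0.2, the removal of genes that share sequence with copies, and the removal of each replicate. The assignment of opposite-strand counts to an overlapping gene, and the removal of sequence copies from the correlation and the coefficient of variation, were added after the data were seen. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used for the remaining steps.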

Results

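The data catalogue the miRNA genes expressed in the embryonic facial prominence of the mouse at embryonic day 12.5, in 2 libraries from separate pools of embryos. Replicate 1 held 11414919 reads and replicate 2 held 12792420 reads. Of these, 4719337 reads (41.3%, exact Clopper-Pearson interval 41.3 to 41.4) lay on the own strand of miRNA genes in replicate 1 and 5929220 reads (46.3%, interval 46.3 to 46.4) in replicate 2. Unmapped reads made up 25.7% and 19.4% of the libraries. Reads with several mapping places made up 26.0% and 27.9%, and reads outside the listed genes 5.57% and 4.72%. No read was ambiguous. Counts were found for 689 miRNA genes in replicate 1 and 723 in replicate 2, and 395 genes were detected with at least 10 counts in both. The detected genes held 99.98% of the gene counts in each library.

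The ranking of genes leaves out reads that map to several places, so genes with copies elsewhere may rank too low. Among the genes as counted, the most abundant was Mir335, at 69100 ± 2984 CPM (SD, n = 2). It was followed by Mir99a at 62091 ± 2067 CPM and by Mir17, a member of the growth-promoting miR-17-92 cluster, at 51655 ± 3519 CPM. Mir214, which is known from skeletal mesenchyme, stood at 45770 ± 198 CPM, and the X-linked Mir322 at 37986 ± 6628 CPM. Further genes of the lists named for cell types were among the 20 highest genes, although which cells gave the reads was not tested. These were Mir126a of endothelium (28130 ± 1273 CPM), Mir182 of sensory cells (15518 ± 198 CPM), Mir140 of cartilage (14833 ± 518 CPM) and Mir143 of smooth muscle (14425 ± 2629 CPM).

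Mir335 (ENSMUSG00000065501.1) lay at chromosome 6, positions 30741299 to 30741396 on GRCm38, in an intron of the imprinted gene Mest. Mir99a (ENSMUSG00000065530.1) lay at chromosome 16, positions 77598936 to 77599000, in an intron of the noncoding gene Mir99ahg. Mir17 lay at chromosome 14, positions 115043671 to 115043754, in an exon of Mir17hg, and Mir214 at chromosome 1, positions 162223368 to 162223477, in an exon of Dnm3os. Mir322 lay at chromosome X, positions 53054255 to 53054349, with no annotated host gene on its strand. Mir140 overlapped an exon of Wwp2 at chromosome 8, positions 107551244 to 107551313. Of the 20 genes, 9 lay in introns, 6 overlapped exons and 5 had no host gene.

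The remaining genes of the 20 included Mir23b at 36095 ± 5.22 CPM, Mirlet7i at 33295 ± 3744 CPM, Mir99b at 31717 ± 4948 CPM, Mirlet7g at 30190 ± 780 CPM and Mir130a at 30156 ± 3800 CPM. Mir26b (25544 CPM), Mir100 (23922 CPM) and Mir30e (23562 CPM) came next, and Mir20a, Mir93 and Mir652 lay between 13707 and 16289 CPM. Mir23b shared a stretch of sequence with Mir23a, and no other of the 20 genes shared one with a copy elsewhere. The 10 highest genes held 42.5% of counts in replicate 1 and 43.3% in replicate 2 (mean 42.9% ± 0.604), and 9 of the 10 were the same genes in both. In each library 13 genes held 50% of all counts. Among the 190 pairs that the 20 genes form, 174 had the same order in both libraries. Of these, 168 also differed by more than the SD of the pair. With n = 2, nearly any pair in the same order meets that limit, so it adds little. With the common coefficient of variation as the error, 136 pairs passed. Mir335 exceeded Mir99a in both libraries, with 66990 against 63553 CPM in replicate 1 and 71210 against 60630 CPM in replicate 2.

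**Figure D1:**
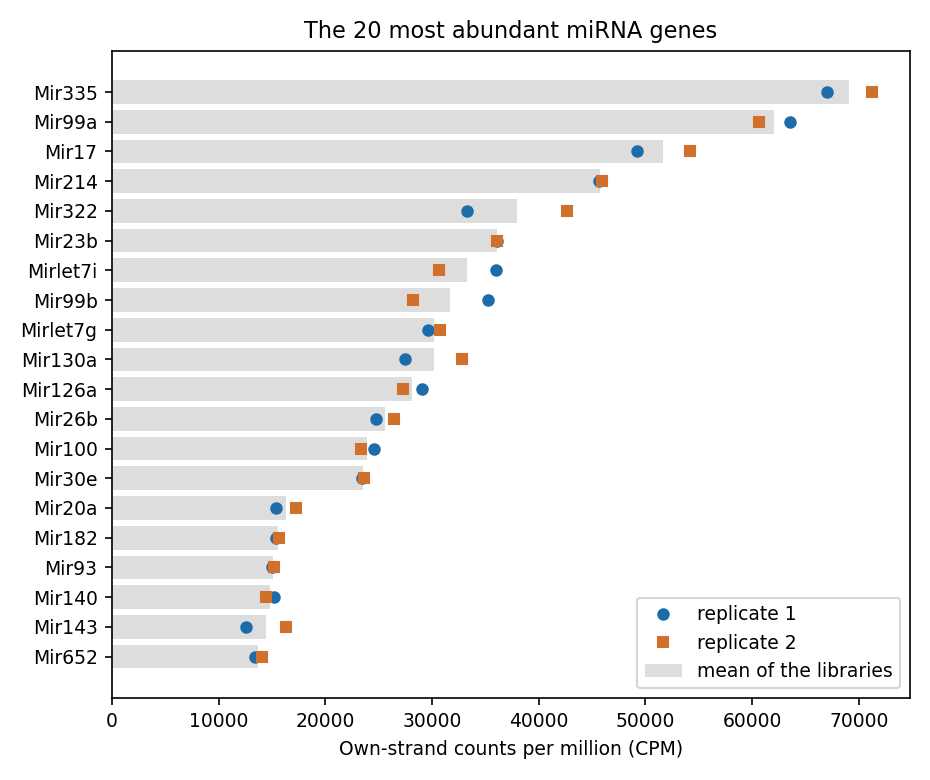
Own-strand CPM (x axis) of the 20 miRNA genes with the highest mean (y axis); grey bars are means of the 2 libraries, circles are replicate 1 and squares are replicate 2. Mir335 leads at 69100 CPM and Mir652 closes the list at 13707 CPM.

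Among the gene lists, those of epithelium, of sensory epithelium and of imprinted loci stood apart as high in the tissue. All 7 epithelial genes were detected and together held 3.33% ± 0.353 of counts (SD, n = 2). Mir429 (9806 ± 1047 CPM), a member of the miR-200 family that maintains epithelial identity, and Mir205 (8883 ± 682 CPM) led the list, followed by Mir203 of stratified epithelium (6070 ± 544 CPM) and Mir200c (4533 ± 552 CPM). The sensory genes Mir182, Mir183 (11146 ± 1769 CPM) and Mir96 (3763 ± 208 CPM), which are transcribed together, held 3.04% ± 0.136. The median of the epithelial list lay at the 99.4 percentile of 10000 random lists of its size. That of the sensory list lay at the 99.2 percentile. The sensory genes form 1 cluster, whereas random lists draw genes singly, so their percentile may overstate how unusual the list is. The same limit holds in part for the epithelial list. Of its genes, 3 lie in a cluster on chromosome 4 and 2 in a cluster on chromosome 6.

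Genes of the Dlk1-Dio3 imprinted cluster on chromosome 12, which are expressed from the maternal chromosome, were detected for 41 of the 46 measured members and held 7.44% ± 0.350 of counts. Their highest members were Mir487b (9216 ± 49.6 CPM), Mir411 (9168 ± 814 CPM), Mir127 (8076 ± 513 CPM) and Mir431 (7477 ± 499 CPM). The list's median lay at the 99.8 percentile, with the same limit, since its genes lie in the same imprinted cluster. The list of other imprinted hosts had all 5 members detected and lay at the 98.2 percentile with 8.28% ± 0.152 of counts. Besides Mir335 it held Mir296 (6413 ± 278 CPM), Mir298 (4004 ± 368 CPM) and Mir483 in an intron of Igf2 (3207 ± 1375 CPM). Mir296 and Mir298 lie in 1 cluster, so the same limit holds in part for this list. With a minimum of 100 counts in place of 10, the epithelial list fell to the 97.4 percentile, the Dlk1-Dio3 list to 86.4 and the other imprinted hosts to 94.9, and none of these then stood apart. The list of other imprinted hosts also fell short, at the 97.2 percentile, when genes that share sequence with copies were removed.

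Shares of counts leave out reads that map to several places, so lists whose genes often share sequence may rank too low. As counted, the miR-17-92 and paralogous clusters held the largest share of any list, 10.9% ± 0.532 of counts, with all 15 genes detected. Mir17, Mir20a (16289 ± 1297 CPM), Mir93 (15090 ± 144 CPM) and Mir106b (9532 ± 956 CPM) led it. Its median lay at the 97.2 percentile, short of the limit, and at 98.6 with replicate 1 left out. The let-7 family, whose members rise as cells differentiate, held 7.23% ± 0.393 with 10 of 10 measured genes detected and lay at the 91.1 percentile. Mirlet7i and Mirlet7g led it, ahead of Mirlet7d (4869 ± 890 CPM) and Mir98 (2449 ± 32.1 CPM). With the 5 let-7 genes that share sequence with a copy removed, the let-7 list lay at the 98.1 percentile.

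Genes of mesenchyme and cartilage held 6.46% ± 0.0329 of counts, with 9 of 11 detected. Most of this share came from Mir214 and Mir140, while Mir455 (1772 ± 189 CPM) and Mir199b (1766 ± 109 CPM) were lower. The list's median lay at the 77.4 percentile, at 38.2 with a minimum of 100 counts and at 93.2 without genes that share sequence with copies. Of the 11 genes, 6 shared sequence with a copy, including Mir199b. Smooth muscle and pericyte genes held 1.47% ± 0.268 (90.5 percentile), almost all from Mir143, with Mir145a at 235 ± 55.3 CPM and 0 counts of Mir145b in both libraries, a count that allows up to 0.636 CPM in replicate 1. Endothelial genes held 2.84% ± 0.125 (56.9 percentile), with Mir126a far above Mir221 (160 ± 17.5 CPM) and Mir222 (110.3 ± 2.20 CPM). With a minimum of 100 counts the endothelial list lay at the 29.4 percentile. None of these lists stood apart.

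**Figure D2:**
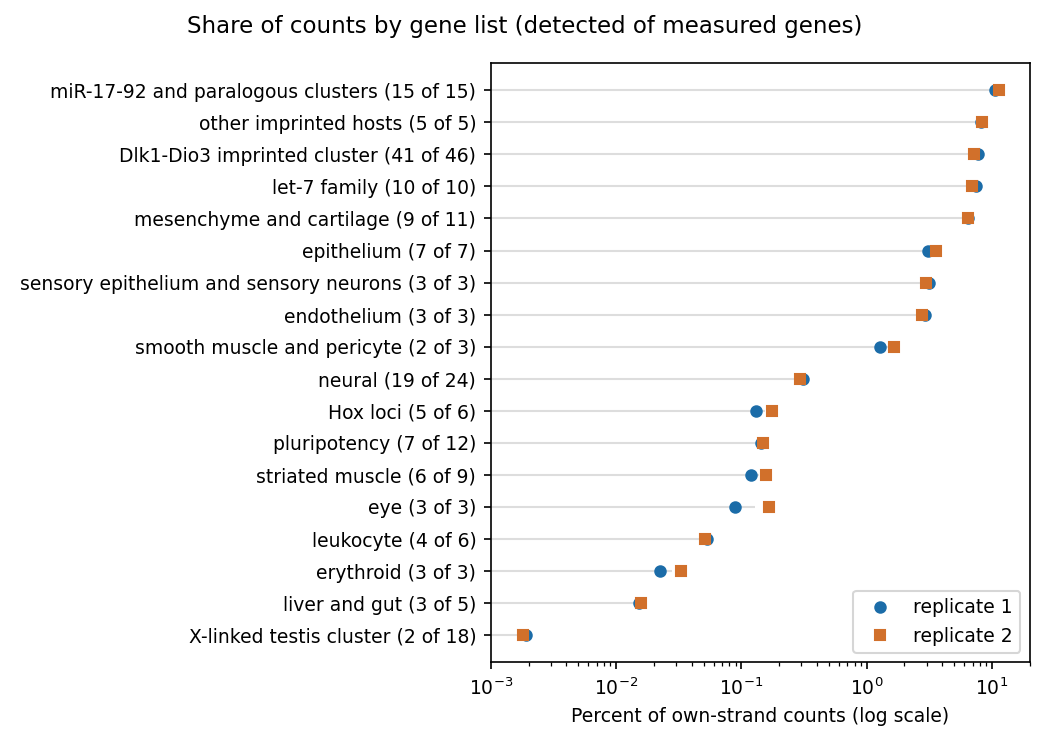
Percent of own-strand gene counts (x axis, log scale) held by each of 18 gene lists (y axis, with the number detected of the number measured); circles are replicate 1, squares are replicate 2, and grey lines run to the mean. Shares run from 0.00186% for the X-linked testis cluster to 10.9% for miR-17-92 and its paralogous clusters.

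Lists of blood, gut, nerve and muscle held small shares of the counts. The erythroid genes Mir451a (239.6 ± 76.4 CPM), Mir486 (19.96 ± 2.94 CPM) and Mir144 (17.5 ± 2.90 CPM) held 0.0277% ± 0.00763 of counts and lay at the 19.3 percentile. The erythroid list lay at the 11.4 percentile with opposite-strand reads assigned and at 6.81 with a minimum of 100 counts. Leukocyte genes held 0.0523% ± 0.00144 (47.4 percentile), with Mir223 of myeloid cells at 292 ± 5.91 CPM, Mir155 at 138 ± 0.581 CPM, Mir146 at 81.7 ± 20.6 CPM and Mir150 at 9.95 ± 0.00587 CPM. With the reads opposite Mir142b counted as Mir142, which then stood at 373 ± 55.5 CPM, the leukocyte share was 0.0879%. Liver and gut genes held 0.0156% ± 0.000488 (36.2 percentile), with Mir192 at 76.0 ± 1.07 CPM, Mir194-2 at 63.4 ± 5.09 CPM, the hepatocyte marker Mir122 at 13.6 ± 0.198 CPM, and Mir215 below the detection minimum. With replicate 2 left out this list lay at the 21.1 percentile. The X-linked testis cluster had 2 of 18 genes detected, Mir741 (9.19 ± 2.51 CPM) and Mir743 (2.73 ± 1.24 CPM), and held 0.00186% ± 6.05e-05 (2.99 percentile, or 5.13 with replicate 1 left out). Its next members, Mir881 (1.61 ± 0.125 CPM) and Mir471 (1.12 ± 0.0856 CPM), were below the detection minimum.

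Neural genes held 0.301% ± 0.0120 of counts (30.2 percentile), with 19 of 24 detected. Mir137, which acts in neurons, stood at 789 ± 6.96 CPM, Mir375 at 745 ± 14.2 CPM, Mir138-1 at 186 ± 12.1 CPM and Mir132 at 154 ± 21.1 CPM. Striated muscle genes held 0.138% ± 0.0263 (6.69 percentile), with 6 of 9 detected, and lay at the 14.5 percentile with replicate 1 left out. Mir206, which is specific to skeletal muscle, stood at 1270 ± 286 CPM, against 61.9 ± 23.9 CPM for Mir208b in an intron of the myosin gene Myh7, 19.3 ± 8.99 CPM for Mir133b and 11.7 ± 6.80 CPM for Mir208a in an intron of Myh6. The best known genes of these tissues, chosen after their values were seen, had low counts. The 3 Mir124a genes, Mir9-2, Mir1a-1 and both Mir133a genes had at most 4 counts in either library, whereas Mir9-3 was detected with 79 and 67 counts. All 8 of these genes shared sequence with a copy elsewhere, as did 17 of the 24 neural and 5 of the 9 striated muscle genes, so these lists are uncertain.

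Pluripotency genes held 0.147% ± 0.00318 (26.6 percentile), with 7 of 12 detected. The miR-302 cluster of early embryonic cells made up most of it, with Mir302a at 525 ± 10.01 CPM, Mir302d at 450 ± 22.1 CPM, Mir302b at 381 ± 7.05 CPM and Mir302c at 57.9 ± 6.64 CPM. Genes at the Hox loci, which are active behind the face, held 0.154% ± 0.0324 (31.6 percentile), with 5 of 6 detected. Of these 6 genes, 2 shared sequence with a copy, and the list lay at the 53.5 percentile with such genes removed. Mir10b, in an intron of both Hoxd3 and Hoxd4, stood at 992 ± 184 CPM, Mir10a at 424 ± 117 CPM, Mir615 at 60.6 ± 16.4 CPM and Mir196b at 58.2 ± 6.46 CPM. The eye genes Mir204 (717 ± 224 CPM), Mir211 (444 ± 265 CPM) and Mir184 (120 ± 63.1 CPM) held 0.128% ± 0.0552 (72.5 percentile). With no count minimum the percentiles of all lists named here rose to 94.6 or above, since genes with no counts then made up most of the background.

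Between the 2 pools, most genes had close levels, and 16 genes differed at least 2-fold beyond counting error, 12 of them higher in replicate 1 and 4 higher in replicate 2. Mir1247, in an exon of Dio3os on chromosome 12, showed the widest gap, with 127 CPM in replicate 1 and 18.2 CPM in replicate 2 (log2 ratio of replicate 2 over replicate 1 of -2.81, exact interval -3.12 to -2.51, exact binomial adjusted p = 2.18e-109). Mir181a-2 followed with 737 and 157 CPM (log2 ratio -2.23, interval -2.34 to -2.13), although it shared sequence with Mir181a-1. Mir208a of heart muscle (-1.26), Mir6240 (-1.22) and Mir92b (-1.13) were also higher in replicate 1. Mir211 (1.29), Mir184 (1.12) and Gm23134 (1.09) were higher in replicate 2, and Gm23134 shared sequence with Mir708.

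Across the 395 detected genes, log2(CPM + 1) correlated between the libraries with a Pearson r of 0.994 (bootstrap interval 0.992 to 0.995) and a Spearman rho of 0.992, over genes, which are not independent replicates. The median absolute log2 ratio was 0.23, and 341 genes (86.3%) lay within 1.5-fold. The common biological coefficient of variation was 0.190 (bootstrap interval 0.156 to 0.220). That interval resamples genes of the same libraries, so it does not cover how the spread would vary between other pools. Counts differed by far more than sampling noise (chi-square of 73700 on 394 degrees of freedom), so the libraries were not 1 library deposited again. With no limit on size, 205 genes differed beyond counting error, 107 higher in replicate 2 and 98 higher in replicate 1.

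The spread between pools limits what these calls show. Simulated pairs of libraries with no changed gene and the fitted coefficient gave 9.81 calls on average, and 4 of 100 draws gave 16 or more, with 18 the highest. That coefficient was fitted to these same 2 libraries, so any real difference between the pools counted as spread. The simulation also gave every gene the same coefficient. When the coefficient was fixed at 0.2 in edgeR's exact test, 2 genes passed, Mir1247 (edgeR adjusted p = 3.73e-07) and Mir181a-2 (edgeR adjusted p = 4.61e-05).

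Of the gene lists, eye and Hox genes were higher in replicate 2 than random lists of the same level. All 3 eye genes were higher in replicate 2 and all 3 differed beyond counting error, with log2 ratios from 0.64 (Mir204) to 1.29 (Mir211). Mir211 and Mir184 were called, both over all detected genes and adjusted over the list alone. These calls cover counting error only, and neither gene passed edgeR's exact test with the coefficient fixed at 0.2. The median of the 3 eye genes, 1.12, lay at the 99.97 percentile of matched random lists (adjusted two-sided share 0.0180). All 5 detected Hox genes were higher in replicate 2, with log2 ratios from 0.22 to 0.56. Their median of 0.50 lay at the 99.92 percentile (adjusted share 0.0180). Of the 5 genes, 0 reached a 2-fold difference, and 3 differed beyond counting error. The median was the ratio of a Mir196a gene, chosen after its values were seen. That gene shared sequence with a copy and was not among the 3. The list difference was not repeated without genes that share sequence.

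Of the striated muscle genes, Mir208a and Mir1b were called higher in replicate 1, Mir1b being chosen after its values were seen and sharing sequence with Mir1a-1, whereas Mir206 (0.46) and Mir133b (0.98), which were not called, had higher values in replicate 2. The list's median of -0.25 lay at the 17.1 percentile (adjusted share 0.615). The smooth muscle list had a median log2 ratio of 0.42 (97.2 percentile) and the erythroid list one of 0.33 (88.1 percentile). The Dlk1-Dio3 list had 27 of 41 genes higher in replicate 1, with a median of -0.08 (2.08 percentile), and the let-7 family 8 of 10, with a median of -0.17 (3.63 percentile). After adjustment over the 18 lists, the shares of these 4 lists and of the 12 others besides eye and Hox were 0.256 or more. Striated muscle was the only list besides eye with called genes.

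**Figure D3:**
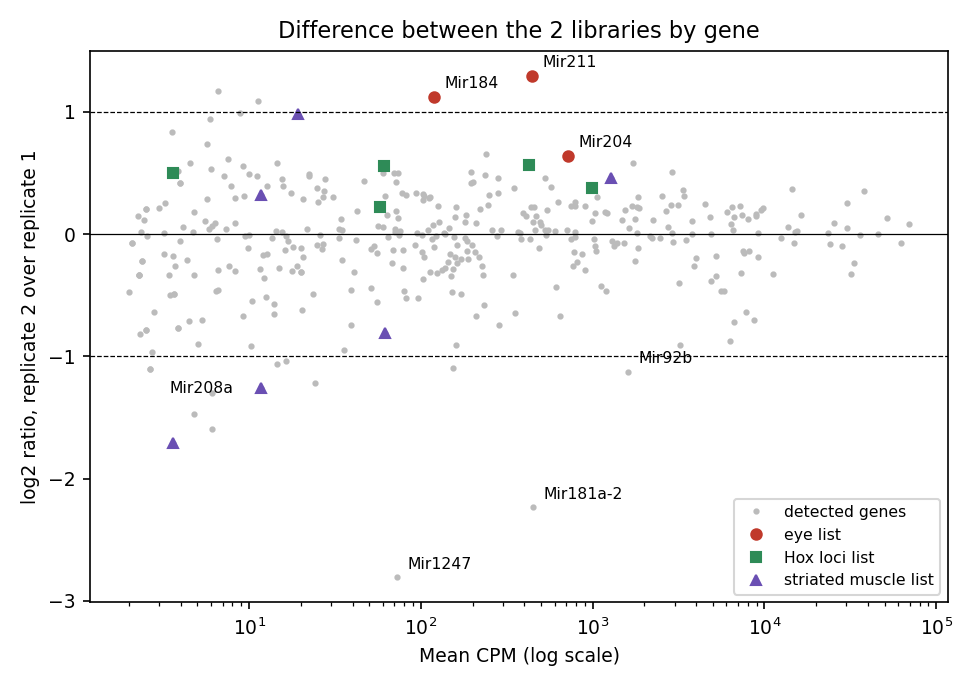
Log2 ratio of replicate 2 over replicate 1 (y axis) against mean CPM (x axis, log scale) for the 395 detected genes (grey dots), with eye genes as circles, Hox loci genes as squares and striated muscle genes as triangles; dashed lines mark ratios of -1 and 1. The 3 eye genes lie between 0.64 and 1.29, and Mir1247 is lowest at -2.81.

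Reads on the strand opposite to a listed gene made up 3.24% of reads on genes in replicate 1 and 3.29% in replicate 2. They were concentrated at a few places. Gm24321, opposite Mir409, had 45795 and 50707 such reads in replicates 1 and 2 and 0 on its own strand. Gm25927, opposite Mirlet7e, had 35917 and 43250, and Gm25301, opposite Mir378a, had 31014 and 46196, again with 0 on their own strands. The 9 genes with at least 1000 opposite-strand reads in each library held 99.5% of all of them, and each overlapped a miRNA gene on the other strand in GENCODE M21.

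Gm25927 lay on the minus strand of chromosome 17, positions 17830343 to 17830459, between Mir99b and Mir125a on the plus strand, and Mirlet7e covered positions 17830352 to 17830444. Mir99b had 166196 and 167311 own-strand reads and Mir125a, chosen after its values were seen, 44766 and 36325, with 0 opposite-strand reads for both genes. Counted as Mirlet7e, the opposite-strand reads came to 7209 ± 219 CPM, rank 36 of all genes. Mir409 would stand at 8830 ± 792 CPM (rank 27) and Mir378a at 6947 ± 831 CPM (rank 40). So counted, the let-7 family held 7.72% in place of 7.23%, the Dlk1-Dio3 cluster 8.62% in place of 7.44%, and the leukocyte list, which gained Mir142, 0.0879% in place of 0.0523%.

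**Figure D4:**
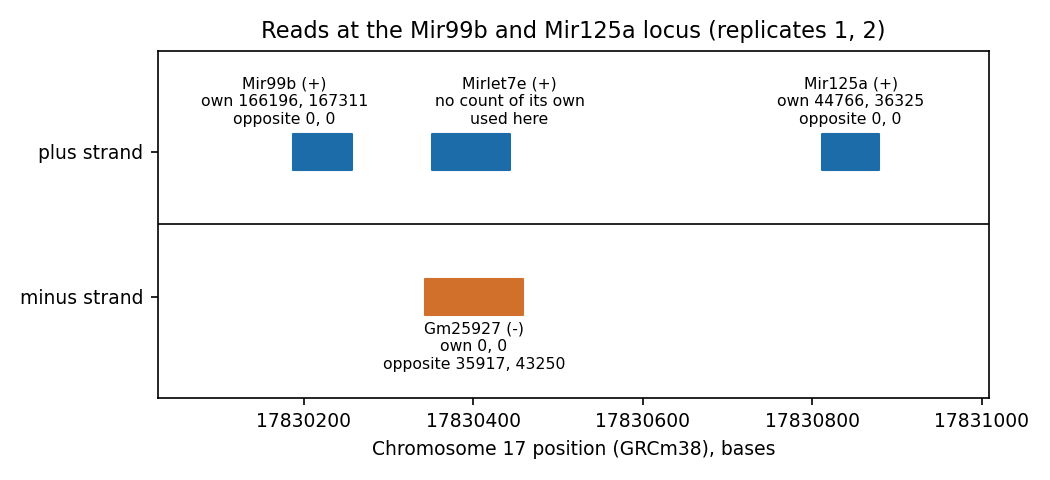
Map of chromosome 17 around Mir99b and Mir125a (x axis, GRCm38 position in bases), with miRNA genes drawn to scale on the plus and minus strands and own-strand and opposite-strand reads given for replicates 1 and 2. Gm25927 has 0 own-strand reads and 35917 and 43250 opposite-strand reads, at the place of Mirlet7e.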

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

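The tests of the opposite-strand reads, of the sequence copies, and of scaling and random lists for the eye genes were chosen after the results were seen. The test of eye tissue was written down before its result was seen. The labels give 1 group, so no biological difference between groups was tested.

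Opposite-strand reads, which the levels of genes do not use, reached at least 1000 in each library at 9 genes and at least 100 at 11 genes. At the 9 genes they came, in both libraries together, to 96502 at Gm24321 (opposite Mir409), 79167 at Gm25927 (Mirlet7e), 77210 at Gm25301 (Mir378a), 32552 at Gm24083 (Mir191), 25181 at Gm25252 (Mir376a), 20111 at Mir299b (Mir299a), 14582 at Gm25750 (Mir380), 8441 at Mir497b (Mir497) and 4156 at Mir142b (Mir142). A general loss of strand was argued against, since at 71 abundant genes with no such overlap opposite-strand reads came to 0.00275% of own-strand reads, against 3.38% over all genes. Of all opposite-strand reads, 99.9% lay on genes that a miRNA gene on the other strand overlaps, although only 32 of the table's genes (1.62%) have such an overlap. The reads may therefore belong to the overlapping genes, for which no count of their own was used here. Whether each read matches the mature strand of that gene was not tested, since reads were not analysed here.

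Of the 8 Mir124a, Mir9, Mir1a and Mir133a genes, Mir9-3 was detected at 14.0 CPM and the others had at most 4 counts in either library, beside higher neural and muscle genes such as Mir137 and Mir206. All 8 of these genes share 20 bases with another place, and of the other list genes the 48 that share were lower than those that do not (median 60.1 against 230.2 CPM, a log2 difference of -1.92, one-sided permutation p = 0.00144). Reads that map to several places and were counted to no gene are therefore a candidate source of the low values. Little neural or muscle RNA stays open as well, because the 11 neural and muscle genes that share nothing had a median of 103 CPM against 237 CPM for 122 other list genes (log2 difference -1.19, two-sided permutation p = 0.33), which decides neither way.

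The 3 eye genes, all detected in both libraries, were higher in replicate 2, with a median log2 ratio of 1.12. Scaling was not put to a real test, since TMM, DESeq2 size factors and total counts moved the ratios by at most 0.00519, and the smallest ratio was 0.64 or more under each. The adjusted share of 0.0180 among random lists is the value that singled the list out, so it does not argue further against chance. More eye tissue in the pool of replicate 2 may account for the pattern but could not be told apart from other causes. The sensory list, which the inner ear and photoreceptors share, had a median log2 ratio of 0.0209, within the median spread of 0.23. Whether eye tissue of this stage expresses the sensory genes was not tested, so this value cannot decide either way. The Hox list was also higher in replicate 2, with a median log2 ratio of 0.50 and the same adjusted share of 0.0180. That median was the ratio of a gene that shared sequence with a copy and did not differ beyond counting error. Whether the 2 patterns have the same cause was not tested. With 1 library per pool, no test can separate a difference in dissection from one in library preparation.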

How the results depend on the processing

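The assignment of opposite-strand reads and the removal of sequence copies from the correlation and the coefficient of variation were added after the data were seen, and the other alternatives were planned. The scalings differed little (TMM factors 0.998 and 1.002), so the same count of 16 differing genes under each says little about stability. No paired analysis was possible because the labels give 1 group. The coefficient of variation stayed within its bootstrap interval, which is over genes only, under the alternatives run. Of the 190 pairs of the 20 highest genes, 136 in place of 168 kept their order beyond the error when the common coefficient of variation was the error. A count of 0 allows up to 0.636 CPM in replicate 1 and 0.506 in replicate 2.

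With at least 1 count in place of 10, 631 genes were detected. The share of the 10 highest genes was 41.5% with counts on both strands and 41.6% without the highest gene, and 42.5 to 43.3% with either replicate left out. The correlation was 0.996 over all genes and 0.991 over genes with at least 100 counts. Genes that differed between the libraries numbered 2 with the coefficient fixed at 0.2 in edgeR's exact test (0 higher in replicate 2 and 2 in replicate 1), and 6 with at least 100 counts (2 and 4), where fewer genes were tested. With all genes that have a count, 23 differed, 7 higher in replicate 2 and 16 in replicate 1.

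With no count minimum, members and background included genes with 0 counts, and list percentiles rose to 100 for mesenchyme and cartilage, neural, miR-17-92 and let-7, 99.4 for striated muscle, 98.5 for smooth muscle, 97.8 for endothelium, 94.6 for erythroid, 99.3 for leukocyte, 99.9 for pluripotency, 99.6 for Hox loci, 98.6 for eye, 97.1 for liver and gut and 96.3 for the testis cluster. With at least 100 counts they were 38.2 for mesenchyme and cartilage, 97.4 for epithelium, 29.4 for endothelium, 86.4 for Dlk1-Dio3, 94.9 for other imprinted hosts, 50.4 for pluripotency, 84.3 for miR-17-92, 65.0 for let-7, 51.1 for eye, 34.7 for striated muscle, 23.8 for leukocyte, 20.6 for Hox loci, 6.81 for erythroid, 6.29 for liver and gut and 3.70 for neural, and the cause was not tested beyond the smaller background. The testis cluster had no gene left there and has no value. Without sequence copies they were 98.1 for let-7, 97.2 for other imprinted hosts, 53.5 for Hox loci, 93.2 for mesenchyme and cartilage, 49.1 for neural, 15.8 for striated muscle, 15.2 for pluripotency and 22.1 for liver and gut. The leukocyte list, near the middle at 47.4, lay at 50.9 with counts on both strands, 52.4 with opposite-strand reads assigned and 51.4 to 51.7 with either replicate left out. miR-17-92 lay at 97.1 to 98.6 with either replicate left out. For differences between the libraries, a minimum of 100 counts gave the 99.3 percentile for smooth muscle, 1.89 for let-7, 4.83 for Dlk1-Dio3 and 48.3 for pluripotency, and the cause was not tested. With counts on both strands, 19 of the 81 named genes moved by more than their SD, all to lower CPM, where opposite-strand reads enlarge the library total.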

Other observations

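The clusters described here, and the repeat of the cluster test without sequence copies, were chosen after the values were seen. The test of cluster mates was written down before its result was seen.

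Neighbouring genes on the same strand differed widely in CPM, although whether their miRNA amounts differed as much was not tested. The 6 genes of the miR-17-92 cluster on chromosome 14, within positions 115043671 to 115044506, ran from 51655 CPM for Mir17 to 26.8 CPM for Mir19b-1, which shares sequence with Mir19b-2. On chromosome X, the 7 detected genes from Mir322 to Mir450-2 held 4.72% of counts, and Mir322 at 37986 CPM stood 3405-fold above Mir450-2 at 11.2 CPM, which shares sequence with a copy. Mir99a and Mirlet7c-1, which lie in introns of the same noncoding gene on chromosome 16, stood at 62091 and 101 CPM, and Mirlet7c-1 shares sequence with other let-7 genes. Reads that map to several places were counted to no gene, so the low members named so far may be undercounted. Mir143 and Mir145a on chromosome 18, which share no such sequence, stood at 14425 and 235 CPM. Mir181d and Mir181c on chromosome 8 were close, at 6634 and 6492 CPM. In all, 43 clusters with 2 or more detected genes, joined over gaps of at most 10000 bases, held 154 genes and 61.8% of counts in replicate 1 and 62.0% in replicate 2.

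Mir181a-2 and Mir181b-2 lie within positions 38852735 to 38853918 of chromosome 2. Mir181a-2 had a log2 ratio of replicate 2 over replicate 1 of -2.23, while Mir181b-2, which shares sequence with Mir181b-1, had 0.23, and the copy Mir181a-1 on chromosome 1 had -0.02. Mir322 (0.35) and Mir351 (-0.72) of the X-linked cluster likewise lay on opposite sides of 0.

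It was asked as a hypothesis whether members of a cluster differ together between the pools. Over 640 pairs of cluster mates, weighted to give each cluster the same weight, the mean absolute difference of log2 ratios was 0.351, against 0.411 when ratios were permuted among genes of like level (one-sided permutation p = 0.101 over 10000 permutations). Without genes that share sequence it was 0.328 against 0.415 (permutation p = 0.0921). The bound written beforehand, under which a p of 0.05 or more would speak against the hypothesis, was wrong, because a p that misses the threshold does not show that the values did not differ. The hypothesis therefore stays open in these libraries.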
